A study of Amia calva with 36 samples.

How the data were processed

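The study measured RNA by sequencing in laser-captured foregut tissue of bowfin embryos reared at 12.8 °C. Per the labels, embryos at stages 24, 25 and 27 were cut into transverse sections of 15 µm, dorsal and ventral endoderm and mesoderm were captured within 2 hours per slide, and cDNA was amplified before library construction. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, aligned with STAR 2.6 and normalized with edgeR, for which no version is given, in R 3.6.0. The deposited table holds log2 CPM (read counts scaled to library size, on the log2 scale) for 21948 bowfin genes in 36 libraries, and 11428 of the genes carry a spotted gar Ensembl identifier.

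The table was tested for its scale. Its smallest value is a log2 of 0.875, or 1.834 CPM, as a prior count of 2 gives, and 2 to the power of the values sums to 1040241 in every library. Library totals and reads were recovered from these relations. Below 200 reads, 100% of the recovered values were whole within 0.02, and values rebuilt from the whole reads differed from the deposited ones by at most 5.0e-09 on the log2 scale. No read was found in any library for 4629 genes, and 0 pairs of libraries were identical. CPM values are recovered reads scaled to the library total. The recovered totals are the reads assigned to genes, 3040 to 1998280 per library (mean 1090731). A count of 0 was given a floor of 3 counts over the reads of the group. Amplified reads are not independent molecules, so floors and folds against them cover counting error only. To compare detection, reads were thinned to 377516 per library, which left out 1 library, and stages were compared with permutation tests of 100000 resamples.

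The 36 libraries were grouped by side, layer and stage into 12 groups of 3. The groups, comparisons, test, named-gene rule and first set of alternative settings were chosen before the data were examined. Deposited log2 CPM values were fitted with limma 3.58.1 (trended moderated test) in R 4.3.3, with a mean for each group and 20 contrasts. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and the threshold was 0.05. A contrast of 1 stage takes its spread from all 36 libraries. Genes with a recovered CPM over 1 in at least 3 libraries were tested, which were 14132 genes, 8409 (59.5%) with a gar identifier. The filter had been planned on the log2 value, but because of the prior count that form removes 0 genes, so recovered CPM was used and the form with no filter became an alternative. The planned count tests with edgeR and DESeq2 were not run because the deposited unit is not counts; limma voom on the recovered reads was added in their place. The 25 gene lists and the list of always-named genes fixed beforehand matched 0 of the identifiers, so their set tests were not run. The rule for named genes takes, in each direction, the called genes with an ortholog symbol that have the largest log2 change, 10 for mean contrasts and 5 for others, and in the mean dorsal-ventral contrasts only those with the same sign at all 3 stages. As the table holds no symbols, a gar identifier took the place of a symbol and at most 2 genes in each direction are printed; where 6 or fewer genes were called, those without a gar identifier were included. Genes that the rule adds where few were called, which are not past the threshold, are left out of the text, apart from 1 whose direction reversed under an alternative.

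The test was tested on simulated data, drawn from negative binomial distributions with the recovered group means and a spread per gene and stage, in which the compared groups were made equal and 100 genes were then changed 4-fold and 100 genes 16-fold. The share of false calls depends on how many genes truly change, which is not known for the real libraries. False calls made up 12.8% of the calls for endoderm against mesoderm, 34.2% and 47% for the mean dorsal-ventral contrasts in mesoderm and endoderm, 76.5% and 79.2% for the dorsal-ventral contrasts at stage 27 in endoderm and mesoderm, and 83.8% for stage 27 against 24 in dorsal mesoderm. The planned test thus did not hold its 5% error rate in the simulation, least of all for contrasts within or between single stages. The simulation did not match the real libraries, however. It gave 169, 210 and 47 false calls for endoderm and mesoderm at stage 27 and for the endoderm mean. The real counts of calls were 48, 170 and 0 in that order. The simulated shares are therefore not error rates of the real calls. Of 100 genes changed 4-fold, 6 to 22 were found.

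Alternatives planned were no filter, a filter at 4 CPM, pseudocounts of 1 and 5 CPM, quantile normalization, median centring, no variance trend, library quality weights, only the groups compared, the replicate number as a fixed or random block, and leaving out each library and each replicate number. Alternatives added after the data were seen were limma voom with and without the library of 3040 reads, limma without that library, the number of genes detected as a covariate, and only the libraries of the stages compared. Each comparison was also repeated on other splits of its libraries, all 10 for 3 against 3 and 100 drawn otherwise. Gene sets picked from these libraries were tested with fry in limma. Figures and permutation tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9; the random block used statmod 1.5.0.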

Results

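RNA was measured in the foregut of bowfin (Amia calva) embryos. The bowfin is a ray-finned fish whose gas bladder, an air-filled organ, buds from the dorsal wall of the foregut, whereas lungs bud from the ventral wall. Dorsal and ventral endoderm and dorsal and ventral mesoderm were collected by laser capture at stage 24, before the gas bladder buds, at stage 25, when it buds, and at stage 27, when it grows out. The 12 groups held 3 libraries each, 36 in all. Libraries held 3040 to 1998280 reads, with a median of 1030874. Replicate 3 of stage 24 ventral endoderm held 3040 reads in 1259 genes, and each of the others held at least 377516. Genes are named by their bowfin identifiers and, where the table gives one, the spotted gar Ensembl identifier of the ortholog. The files do not pair these identifiers with gene names, so no gene family or pathway is described. Regions were cut from the same transverse sections and the labels do not tie libraries to embryos, so the p-values measure only the spread between these libraries.

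Stage 27 libraries held reads of many more genes than libraries of the earlier stages. At an equal depth of 377516 reads, 9959 ± 1429 genes had a read at stage 27 (SD, n = 12), 3884 ± 796 at stage 25 (n = 12) and 4680 ± 1933 at stage 24 (n = 11, without the library of 3040 reads). The ratio of stage 27 to stage 24 was 2.13 and that of stage 27 to stage 25 was 2.56 (two-sided permutation tests, p = 2e-05 for each, the smallest that these permutations can give; adjusted p = 3e-05 over 3 comparisons). Stages 25 and 24 were not told apart (permutation p = 0.204, adjusted p = 0.204). Libraries were permuted as independent units although regions were cut from the same sections, so these p-values may be too small. Library numbers ran in separate blocks by stage, so stage cannot be separated from a batch. One gene, AMCG00006382, had the most reads in 35 of the 36 libraries. Its share of reads was 13.9% ± 5 at stage 24, 14.5% ± 3.13 at stage 25 and 5.89% ± 1.91 at stage 27 (SD, n = 12 each). The first principal component held 24.8% of the variance and the second 5.63%. Within stages 24, 25 and 27 the first component followed the number of genes detected, with Pearson r of 0.99, 0.98 and 0.98 (permutation p = 1e-05, 1e-05 and 2e-05; adjusted p = 2e-05, 2e-05 and 3e-05 over 6 relations; n = 12 each). Spearman rho was 0.99, 0.92 and 0.92 (permutation p = 1e-05, 8e-05 and 4e-05; adjusted p = 2e-05, 8e-05 and 5e-05). A p of 1e-05 is the smallest that these permutations can give. Without the 2 libraries farthest from the median number of genes, r was 1.0, 0.94 and 0.98. Genes without a read share 1 smallest value. On average they made up 66.7%, 69.5% and 24.2% of the tested genes of a library at stages 24, 25 and 27. A component that tracks detection is thus partly built into these values.

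**Figure D1:**
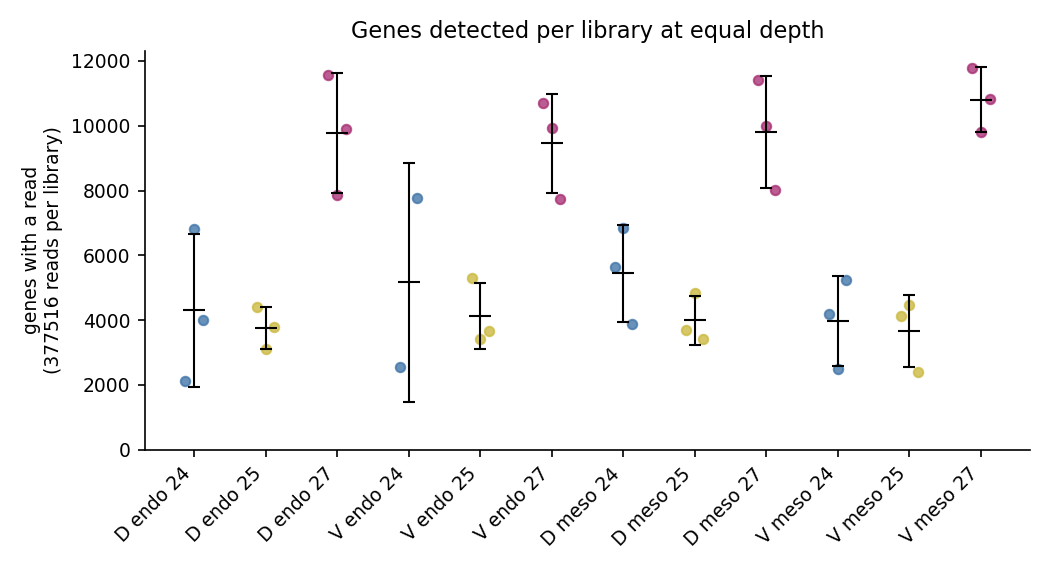
Number of genes with at least 1 read in each library at an equal depth of 377516 reads (y axis) for the 12 groups (x axis; D, dorsal; V, ventral; endo, endoderm; meso, mesoderm; the number is the stage). Dots are libraries, blue at stage 24, yellow at stage 25 and purple at stage 27, and bars are the mean ± SD; stage 27 averaged 9959 genes against 4680 at stage 24 and 3884 at stage 25.

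Endoderm and mesoderm were compared over both sides and all 3 stages, to show how far the captured layers differed. With limma, 574 of 14132 genes differed (adjusted p under 0.05), 167 higher in endoderm and 407 higher in mesoderm, and 347 of them had a gar ortholog. AMCG00003274 (ENSLOCG00000012022) averaged 417 ± 434 CPM in endoderm and 34.5 ± 94.6 CPM in mesoderm (SD, n = 18 each), a log2 difference of 5.41 (SE 0.68, adjusted p = 1.41e-05), with reads in 18 of 18 endoderm and 10 of 18 mesoderm libraries. AMCG00018072 (ENSLOCG00000001033) averaged 502 ± 401 CPM in endoderm and 26.9 ± 34.1 CPM in mesoderm, a log2 difference of 4.79 (SE 0.77, adjusted p = 0.000205). AMCG00017661 (ENSLOCG00000010614) was higher in mesoderm, at 461 ± 405 CPM against 90.3 ± 252 CPM (log2 difference -5.19, SE 0.71, adjusted p = 2.66e-05), and had reads in 18 of 18 mesoderm and 12 of 18 endoderm libraries. AMCG00020466 (ENSLOCG00000005226) was higher in mesoderm as well, at 1140 ± 603 CPM against 134 ± 238 CPM (log2 difference -4.82, SE 0.64, adjusted p = 2.13e-05). The sign was the same in 6 of 6 region and stage pairs for 78 of the 167 endoderm-higher genes and for 127 of the 407 mesoderm-higher genes. Signs were taken without a tolerance, so a pair without a read in either layer counted as 0 or took its sign from rounding. The remaining genes therefore need not change direction between pairs. In simulated data 14 of 109 calls of this comparison (12.8%) were false, and 73 of 100 genes changed 16-fold were found. Leaving out replicate number 1, 2 or 3 throughout gave 209, 108 and 114 calls. The balance between layers depended on the method: limma voom on the reads gave 930 calls, 798 higher and 132 lower in endoderm. Without the library of 3040 reads it gave 1192, 541 higher and 651 lower in endoderm, which included 568 of the 574.

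The genes of the 2 layers took up different shares of the reads. These genes were chosen on the same libraries, so their shares are not independent evidence of a difference between layers. The 167 endoderm-higher genes took 3.6% ± 0.0902 of the reads of dorsal endoderm and 3.82% ± 0.824 of those of ventral endoderm at stage 27 (SD, n = 3), and 0.327% ± 0.0716 and 0.73% ± 0.0557 of those of dorsal and ventral mesoderm. The 407 mesoderm-higher genes took 8.38% ± 0.0289 and 8.15% ± 0.867 of the reads of dorsal and ventral mesoderm at stage 27, and 1.11% ± 0.0709 and 0.889% ± 0.643 of those of dorsal and ventral endoderm. Between ventral and dorsal mesoderm at stage 27 the share of endoderm-higher genes differed by a ratio of 2.23, with no overlap between libraries. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.8 over 12 tests). Of the 167 genes, 146 were lower in dorsal than in ventral mesoderm, by a median log2 difference of -1.1; fry, limma's rotation test of a gene set, gave an adjusted p of 0.48.

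**Figure D2:**
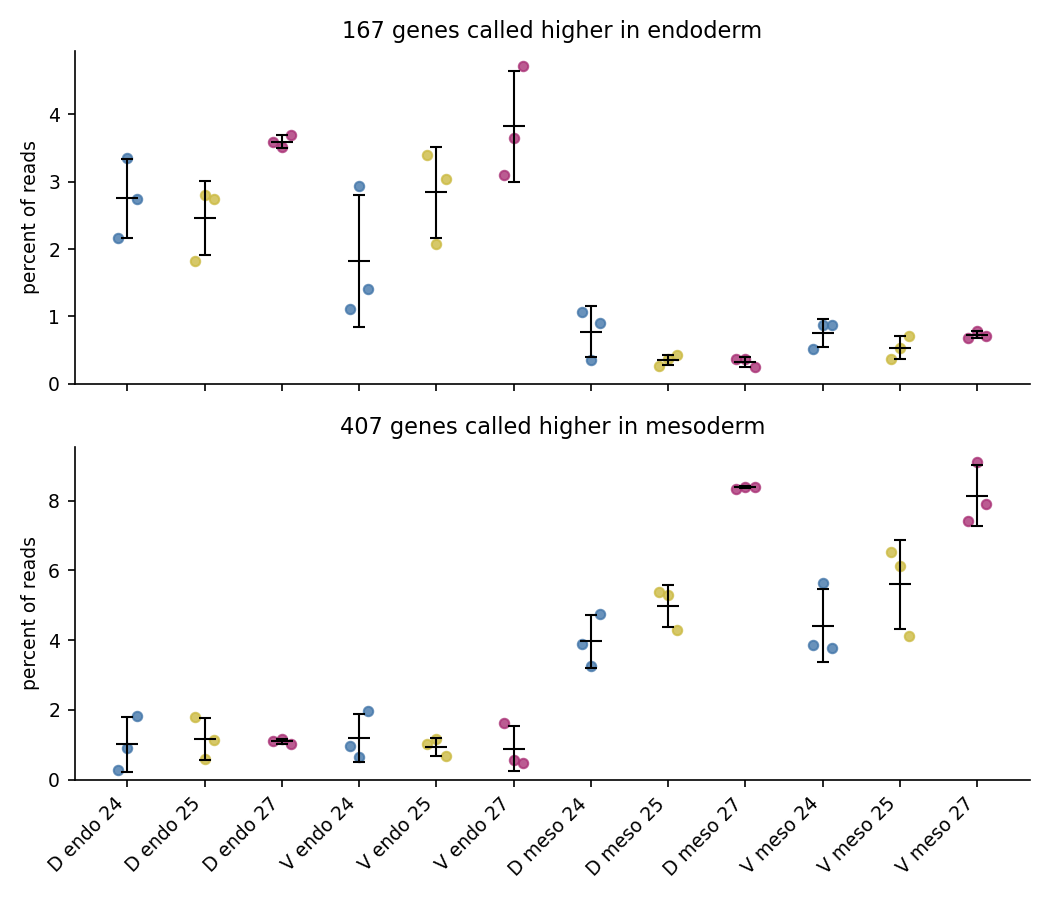
Percent of each library's reads (y axis) in the 167 genes called higher in endoderm (top) and the 407 called higher in mesoderm (bottom), for the 12 groups (x axis; D, dorsal; V, ventral; endo, endoderm; meso, mesoderm; the number is the stage). Dots are libraries, blue at stage 24, yellow at stage 25 and purple at stage 27, and bars are the mean ± SD; at stage 27 the mesoderm-higher genes averaged 8.38% of dorsal and 8.15% of ventral mesoderm reads.

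Dorsal and ventral mesoderm were compared as a mean over the 3 stages, to show which genes marked the side from which the gas bladder grows. With limma, 38 genes differed, 16 higher dorsally and 22 higher ventrally, and 27 had a gar ortholog. AMCG00006763 (ENSLOCG00000016391) had reads in 9 of 9 dorsal and 3 of 9 ventral libraries (log2 difference 4.32, SE 0.80, adjusted p = 0.00531). It averaged 173 ± 108, 179 ± 85.1 and 305 ± 67 CPM in dorsal mesoderm at stages 24, 25 and 27 (SD, n = 3 each), against 0, 0 and 294 ± 101 CPM in ventral mesoderm. AMCG00006592 (ENSLOCG00000016436) averaged 321 ± 401, 79.1 ± 85.4 and 23.6 ± 19.5 CPM dorsally and 0, 0 and 1.59 ± 1.58 CPM ventrally (log2 difference 4.26, SE 0.74, adjusted p = 0.00267), with reads in 9 of 9 dorsal libraries. AMCG00007629 (ENSLOCG00000014158) was higher ventrally, at 145 ± 163, 320 ± 408 and 40.6 ± 28.6 CPM against 0, 0.255 ± 0.442 and 2.35 ± 4.08 CPM (log2 difference -4.69, SE 0.95, adjusted p = 0.0129), with reads in 8 of 9 ventral libraries. AMCG00016888 (ENSLOCG00000011829) was higher ventrally too, at 137 ± 167, 137 ± 165 and 54 ± 2.86 CPM against 0.893 ± 1.55, 0 and 0 CPM (log2 difference -4.41, SE 0.78, adjusted p = 0.003), with reads in 7 of 9 ventral libraries. In simulated data 27 of 79 calls of this comparison (34.2%) were false, and 44 of 100 genes changed 16-fold were found. The count was 24 without replicate 2 of stage 24 dorsal mesoderm, 22 and 25 without replicates 1 and 3 of stage 24 ventral mesoderm, 24 without replicate 1 of stage 25 ventral mesoderm and 80 with no filter on low values. It was 12 with only the groups compared (2 higher and 10 lower dorsally), 7 of them among the 38, and 21 with median centring. Limma voom gave 16 and, without the library of 3040 reads, 40, of which 27 were among the 38.

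By stage, dorsal and ventral mesoderm differed in 3 genes at stage 24, 6 at stage 25 and 170 at stage 27 with limma. At stage 27, 78 genes were higher dorsally and 92 ventrally, and 105 had a gar ortholog. AMCG00008538 (ENSLOCG00000008170) averaged 1630 ± 681 CPM in ventral mesoderm, in 3 of 3 libraries, and 1.96 ± 3.4 CPM in dorsal mesoderm (SD, n = 3), an 832-fold ratio of means (log2 difference -9.03, SE 0.98, adjusted p = 8.4e-08). AMCG00004620 (ENSLOCG00000006231) averaged 292 ± 143 CPM ventrally and had no read dorsally, at least 281-fold higher against a floor of 3 counts over the group (log2 difference -7.17, SE 1.22, adjusted p = 0.000288). AMCG00012666 (ENSLOCG00000015474) was higher dorsally, at 243 ± 275 CPM against 0.569 ± 0.985 CPM (log2 difference 6.10, SE 0.89, adjusted p = 2.32e-05). AMCG00004155 (ENSLOCG00000015840) averaged 290 ± 134 CPM dorsally and 6.83 ± 11.8 CPM ventrally (log2 difference 6.01, SE 1.51, adjusted p = 0.0289). Of the 170 genes, 132 had no read in the mesoderm of stage 24 and 130 none in that of stage 25.

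The stage 27 count depended on which libraries gave the spread. In simulated data 210 of 265 calls of this comparison (79.2%) were false. These outnumber the 170 genes called in the real data, so the share does not carry over to them. With the 12 stage 27 libraries alone, a fit chosen after the first result was seen, 30 genes differed, 5 higher dorsally and 25 ventrally, and 15 of them were among the 170. Of the 25, 9 were higher in endoderm than in mesoderm at an unadjusted p under 0.05. In simulated data this fit called 49 changed and 12 unchanged genes. AMCG00008538 and AMCG00004620 passed in this fit (adjusted p = 0.00136 and 0.0108; over the 16 alternatives 5.67e-10 to 0.149 and 7.77e-06 to 0.227), and AMCG00012666 and AMCG00004155 did not (adjusted p = 0.0568 for each; 6.14e-06 to 0.447 and 0.000518 to 0.447). Limma voom gave 5 genes, and 22 without the library of 3040 reads, 19 of them among the 170; limma with the 6 compared libraries alone gave 0 (996 with an unadjusted p under 0.05). The count was 84 with quantile normalization, 86 with a filter at 4 CPM, 112 with median centring (84 higher and 28 lower dorsally) and 318 with no filter. Of the 3 genes at stage 24, AMCG00006945 averaged 383 ± 474 CPM dorsally and 0.205 ± 0.356 CPM ventrally (adjusted p = 0.0181). AMCG00005387 averaged 7.55 ± 4.29 CPM dorsally and 0 CPM ventrally (adjusted p = 0.0181). The other was AMCG00019538 (ENSLOCG00000012876), with 0 CPM against 45.5 ± 26.5 CPM (adjusted p = 0.0253). At stage 25 AMCG00006920 (ENSLOCG00000016590) averaged 273 ± 326 CPM dorsally and 0 CPM ventrally (adjusted p = 0.0281), and AMCG00002607 (ENSLOCG00000009194) averaged 0.255 ± 0.442 CPM dorsally and 1240 ± 982 CPM ventrally (adjusted p = 0.0202). With the libraries of the stage alone, limma called 0 genes at stage 24 and 0 at stage 25 (554 and 516 with an unadjusted p under 0.05). Limma voom on all 36 libraries called 17 and 85, or 32 and 166 without the library of 3040 reads. Leaving out single libraries gave 1 to 33 genes at stage 24 and 5 to 27 at stage 25. Limma with a fixed replicate block called 0 genes at stage 24 (smallest adjusted p 0.0501).

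**Figure D3:**
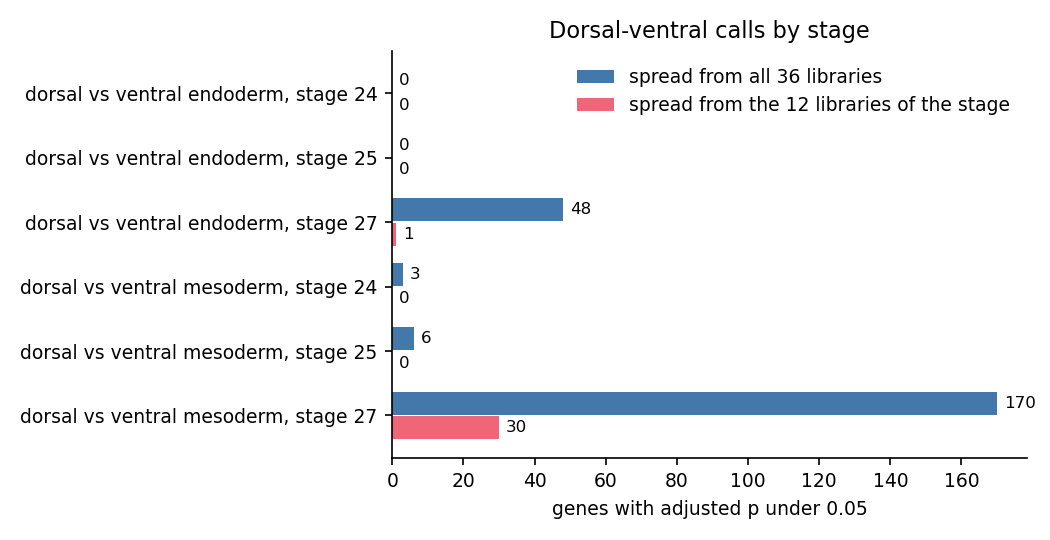
Number of genes with adjusted p under 0.05 (x axis) between the dorsal and ventral side of each layer at each stage (y axis), with the spread taken from all 36 libraries or from the 12 libraries of the stage. At stage 27 the mesoderm count was 170 with all libraries and 30 with those of the stage, and the endoderm count 48 and 1.

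**Figure D4:**
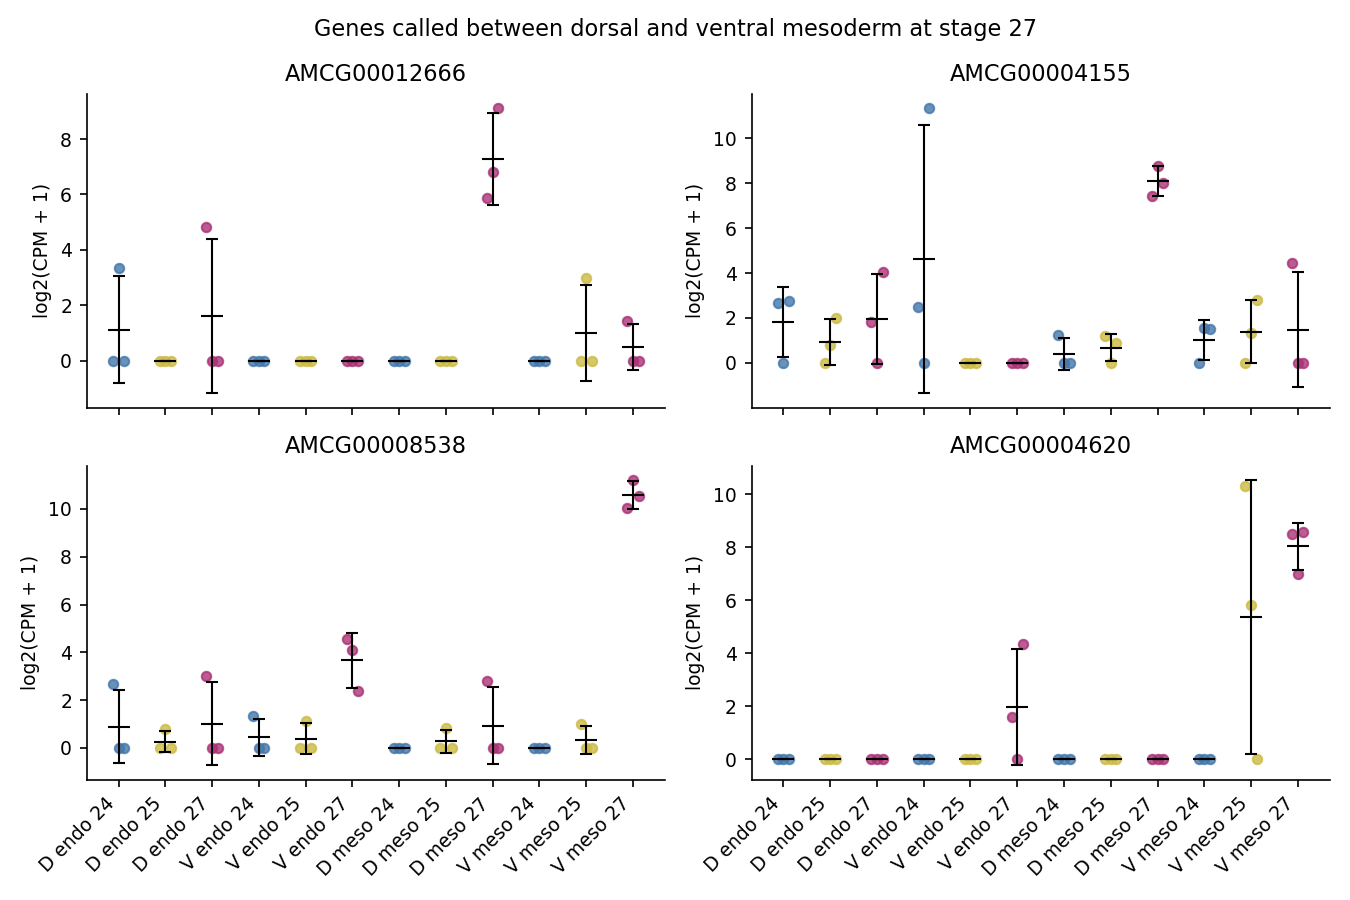
Log2 of CPM plus 1 (y axis) of the 4 named genes of the stage 27 comparison of dorsal and ventral mesoderm, for the 12 groups (x axis; D, dorsal; V, ventral; endo, endoderm; meso, mesoderm; the number is the stage). Dots are libraries, blue at stage 24, yellow at stage 25 and purple at stage 27, and bars are the mean ± SD; AMCG00008538 averaged 1630 CPM in ventral and 1.96 CPM in dorsal mesoderm at stage 27.

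Dorsal and ventral endoderm were compared in the same way. As a mean over the 3 stages, no gene passed with limma, 650 of the 14132 had an unadjusted p under 0.05, and the smallest adjusted p was 0.405. Limma called 8 genes with only the groups compared (7 higher and 1 lower dorsally) and 8 with no filter on low values (5 higher, 3 lower). Limma voom called 1 gene, and 0 without the library of 3040 reads. At stage 24 limma called 0 genes (684 with an unadjusted p under 0.05). Limma called 14 with library quality weights, 3 with no variance trend and 2 without the library of 3040 reads. Limma voom called 8033, and 4 without that library. At stage 25 limma called 0 genes (853 with an unadjusted p under 0.05, smallest adjusted p 0.0548) and limma voom 44, or 74 without the library of 3040 reads. In 7 alternatives that kept all compared libraries, limma called 1 to 6 genes at stage 25. Leaving out single compared libraries gave 3 to 12. Leaving out replicate numbers 1, 2 and 3 gave 3, 20 and 0. At stage 27 limma called 48 genes, 29 higher dorsally and 19 ventrally. AMCG00000970 (ENSLOCG00000008406) averaged 44.2 ± 17.6 CPM dorsally and 0.886 ± 1.53 CPM ventrally (SD, n = 3; log2 difference 4.15, SE 0.59, adjusted p = 8.7e-05). AMCG00000379 (ENSLOCG00000011504) averaged 113 ± 147 CPM dorsally and 3.8 ± 5.83 CPM ventrally (log2 difference 4.02, SE 0.84, adjusted p = 0.0134). AMCG00009086 (ENSLOCG00000007258) had no read dorsally and 54.3 ± 53.9 CPM ventrally, at least 60.4-fold higher (log2 difference -4.37, SE 0.56, adjusted p = 1.04e-05). AMCG00018151 (ENSLOCG00000001695) averaged 2.21 ± 2.79 CPM dorsally and 51.2 ± 34.8 CPM ventrally (log2 difference -3.66, SE 0.56, adjusted p = 0.000142). With the stage 27 libraries alone 1 gene passed, none of the 48. Limma voom on all 36 libraries called 0 (253 with an unadjusted p under 0.05). In simulated data 169 of 221 calls of this comparison (76.5%) were false. These outnumber the 48 genes called in the real data, so the share does not carry over to them. The count was 10 with quantile normalization, 14 with median centring, 26 with a filter at 4 CPM, 73 with library quality weights, 109 with no filter and 0 with only the groups compared (492 with an unadjusted p under 0.05). It was 81 and 98 without replicates 1 and 2 of stage 27 dorsal endoderm and 91 and 79 without replicates 1 and 2 of stage 27 ventral endoderm.

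AMCG00016115 (ENSLOCG00000008539) was that 1 gene, and was chosen here after its values were seen. At stage 27 it averaged 230 ± 96 CPM in dorsal and 5.01 ± 4.62 CPM in ventral endoderm, and 1490 ± 128 CPM in dorsal and 55.6 ± 31 CPM in ventral mesoderm (SD, n = 3 each). With the stage 27 libraries alone the log2 difference was 5.23 in endoderm (SE 0.69, adjusted p = 0.00917) and 4.87 in mesoderm (SE 0.69, adjusted p = 0.00658), with the 3 dorsal libraries above the 3 ventral ones in each layer. With all 36 libraries it did not pass in either layer (adjusted p = 0.26 and 0.219). Its ratio of endoderm to mesoderm CPM was 15.5% dorsally and 9.02% ventrally. Among mesoderm-higher genes with at least 20 CPM in the mesoderm of that side, 78 of 342 had a ratio as high dorsally (median 5.67%, quartiles 1.67% and 14.5%) and 110 of 309 ventrally (median 6.43%, quartiles 1.73% and 12.6%). Mesoderm reads in the endoderm captures are therefore not excluded as the source of its endoderm values at stage 27. At stage 25 it averaged 45.7 ± 58.2 CPM in dorsal and 26.5 ± 46 CPM in ventral endoderm and had no read in mesoderm. Between the calls of the 2 layers at stage 27, 3 genes were shared, where 0.577 would be shared by chance. All 3 had the same direction, where 0.284 would share gene and direction. These chance values treat the calls as independent, but both lists came from 1 fit with the same spread per gene. The excess is therefore not evidence of a shared difference. The 170 mesoderm calls tested as a set in endoderm with fry gave an adjusted p of 0.139, and the 48 endoderm calls tested in mesoderm gave 0.25. Tested without regard to direction, fry gave unadjusted p of 0.021 and 2.86e-05 in that order. Both sets were picked in the fit whose spread this test uses, which favours genes of small spread. These 2 values are therefore not evidence of a shared difference either.

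Stage 27 was compared with stage 24 in each region, to show what differed between the stage before budding and that of outgrowth. Library numbers in the labels ran in separate blocks for each stage. Stage therefore cannot be separated from embryo or from a batch of capture, amplification or library making. With limma, 363 genes differed in dorsal endoderm (358 higher at stage 27, 5 lower), 627 in dorsal mesoderm (610 higher, 17 lower), 244 in ventral endoderm (241 higher, 3 lower) and 975 in ventral mesoderm (973 higher, 2 lower). AMCG00009551 (ENSLOCG00000006200) averaged 989 ± 92.2 CPM in dorsal and 1120 ± 393 CPM in ventral endoderm at stage 27, against 1.26 ± 1.33 and 1.03 ± 1.78 CPM at stage 24 (SD, n = 3; adjusted p = 0.00039 and 0.000226). AMCG00021160 (ENSLOCG00000013751) averaged 605 ± 230 and 678 ± 86.5 CPM in dorsal and ventral endoderm at stage 27 and had no read at stage 24. These means were 451-fold and 307-fold above the counting floor. AMCG00018336 (ENSLOCG00000009053) averaged 767 ± 48.8 CPM in dorsal and 3090 ± 757 CPM in ventral mesoderm at stage 27, against 0 and 17.5 ± 27.2 CPM at stage 24 (adjusted p = 0.00161 and 0.00179). AMCG00008538 had no read in ventral mesoderm at stage 24 and 1630 ± 681 CPM at stage 27, 1470-fold above the counting floor (adjusted p = 6.59e-09). Such floors cover counting error only: even among the 1000 most abundant genes, 8.2% of the values at stage 24 were 0. These folds are therefore not lower bounds on the change. Among the few genes lower at stage 27, AMCG00007895 (ENSLOCG00000014628) averaged 3.53 ± 6.11 CPM in dorsal mesoderm against 641 ± 890 CPM at stage 24 (log2 difference -6.44, SE 1.82, adjusted p = 0.0311). AMCG00012934 (ENSLOCG00000015745) averaged 1.71 ± 2.97 CPM in dorsal endoderm against 383 ± 591 CPM (log2 difference -5.21, SE 1.42, adjusted p = 0.0348). Over the 4 regions 3 genes were called higher at stage 27 in all 4, and 1457 in 1 region.

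The size of these stage counts depended on the scaling and on which libraries gave the spread, and the number of genes detected moved with stage. Of the calls higher at stage 27, 97.8% in dorsal endoderm, 96.4% in dorsal mesoderm, 97.9% in ventral endoderm and 98.2% in ventral mesoderm had no read in 2 or 3 of the 3 stage 24 libraries. The median of all tested genes was higher at stage 27 by a log2 value of 1.31, 0.95, 1.33 and 1.61 in the same order of regions. The median gene had no read in 9 of 12 libraries at stage 24 and in 0 of 12 at stage 27, so centring on the median subtracts the difference in detection and its change of direction says nothing about scaling. When each library was centred on its median, 2364, 2454, 1490 and 3326 genes differed, of which 19, 72, 27 and 43 were higher at stage 27 and 2345, 2382, 1463 and 3283 lower. With quantile normalization, after which the medians were -0.06, -0.09, -0.04 and -0.09, 32, 148, 17 and 118 genes differed, of which 19, 110, 15 and 97 were higher. With the number of genes detected as a covariate, chosen after the result was seen, the counts were 95, 331, 52 and 181, of which 75, 316, 29 and 174 were higher at stage 27 and 20, 15, 23 and 7 lower. With only the groups compared, limma called 0 genes in dorsal endoderm (2606 with an unadjusted p under 0.05), 7 in dorsal mesoderm, 0 in ventral endoderm (2351) and 2760 in ventral mesoderm. With library quality weights it called 831, 551, 2260 and 1679. Limma voom called 54, 184, 2740 and 686, and 414, 570, 182 and 1327 without the library of 3040 reads. In ventral endoderm 7 of the 2740 were higher at stage 27 and 2733 lower, against 181 and 1 of the 182. In simulated data 306 of 365 calls in dorsal mesoderm (83.8%) were false. Without stage 24 replicates 1, 2 and 3 in turn, the count was 131, 228 and 103 in dorsal endoderm, 63, 495 and 62 in ventral endoderm and 453, 423 and 536 in ventral mesoderm. It was 371 and 324 in dorsal mesoderm without stage 24 replicates 1 and 3, and 594 and 634 in ventral mesoderm without stage 27 replicates 1 and 3.

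The steps between stages were compared on the dorsal side, where the gas bladder forms. From stage 24 to stage 25, limma called 0 genes in dorsal endoderm (847 with an unadjusted p under 0.05, smallest adjusted p 0.0978; limma voom 22, or 36 without the library of 3040 reads; limma with quantile normalization 7) and 5 in dorsal mesoderm (1 higher, 4 lower at stage 25). AMCG00006920 rose from 0 to 273 ± 326 CPM in dorsal mesoderm (SD, n = 3; adjusted p = 0.045). AMCG00015888 (ENSLOCG00000013638) averaged 489 ± 632 CPM at stage 24 and 0 CPM at stage 25 (adjusted p = 0.045) and AMCG00006945 averaged 383 ± 474 CPM and 0 CPM (adjusted p = 0.0123). These 3 genes passed in 11, 7 and 14 of the 15 alternatives in that order (adjusted p from 0.000681, 9.98e-05 and 7.17e-05 to 0.845 in each). With a pseudocount of 1 CPM 2 genes were called, 0 of them higher at stage 25. From stage 25 to stage 27, 423 genes differed in dorsal endoderm (421 higher, 2 lower at stage 27) and 823 in dorsal mesoderm (817 higher, 6 lower). AMCG00016115 averaged 1490 ± 128 CPM in dorsal mesoderm at stage 27 and had no read at stage 25, 2040-fold above the counting floor (adjusted p = 0.00017). This fold is not a lower bound, since 7.5% of the values of the 1000 most abundant genes were 0 at stage 25. AMCG00009551 rose in dorsal endoderm from 8.75 ± 10.6 to 989 ± 92.2 CPM (adjusted p = 0.00228). After median centring, where the median gene had no read in 12 of 12 libraries at stage 25, the stage 27 and 25 counts were 2735 in endoderm (19 higher, 2716 lower) and 2671 in mesoderm (55 higher, 2616 lower). They were 24 and 128 with quantile normalization and 73 and 259 with the number of genes detected as a covariate. With only the groups compared they were 1085 and 348, with library quality weights 1100 and 960, and with only the libraries of the stages compared 826 and 1020. Limma voom gave 867 and 1141, or 1757 and 2525 without the library of 3040 reads. Without single libraries the stage 25 and 24 counts ranged from 0 to 17 in endoderm and 9 to 31 in mesoderm. The stage 27 and 25 counts fell to 178, 165 and 157 without stage 25 dorsal endoderm replicates 1, 2 and 3, and to 264 without stage 27 dorsal endoderm replicate 1. In mesoderm they fell to 396, 500 and 377 without stage 25 dorsal mesoderm replicates 1, 2 and 3, and to 508 without stage 27 dorsal mesoderm replicate 1.

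Whether the dorsal-ventral difference itself differed between layers or stages was tested with interaction terms. Between endoderm and mesoderm, no gene passed with limma (669 with an unadjusted p under 0.05, smallest adjusted p 0.126; limma voom 0, or 8 without the library of 3040 reads). Limma called 18 genes with no filter on low values, 2 with no variance trend and 2 with a pseudocount of 5 CPM. Between stages 27 and 24, 35 genes passed in mesoderm, 12 with a larger and 23 with a smaller dorsal-minus-ventral value at stage 27. AMCG00008538 had a log2 difference of -9.03 between these stages (SE 1.38, adjusted p = 4e-04), and AMCG00002893 (ENSLOCG00000005811) one of -6.55 (SE 0.79, adjusted p = 2.55e-06). AMCG00002893 averaged 186 ± 101 CPM in ventral mesoderm at stage 27 (SD, n = 3), with no read in dorsal mesoderm at that stage or in either side at stage 24. AMCG00012666 gave 6.10 (SE 1.26, adjusted p = 0.0151) and AMCG00017755 (ENSLOCG00000013308) 5.95 (SE 1.40, adjusted p = 0.0499). In endoderm 2 genes passed, AMCG00016191 (ENSLOCG00000007930) with 3.49 (SE 0.61, adjusted p = 0.015) and AMCG00009086 with -4.37 (SE 0.79, adjusted p = 0.0161). Apart from AMCG00017755, these named genes had no read on either side of their layer at stage 24. Their terms therefore repeat the stage 27 difference. With fewer genes detected at stage 24, they cannot show that the dorsal-ventral difference changed with stage. With the libraries of stages 24 and 27 alone, limma called 11 genes in mesoderm and 0 in endoderm (501 with an unadjusted p under 0.05). Limma voom on all 36 libraries called 1 and 103, or 11 and 0 without the library of 3040 reads. The mesoderm count was 54, 66 and 68 without stage 27 dorsal replicates 1, 2 and 3, 62, 70 and 67 without stage 27 ventral replicates 1, 2 and 3 and 23 without stage 24 ventral replicate 1. It was 8 with only the groups compared, 17 with quantile normalization, 19 with median centring and with a filter at 4 CPM, 53 with a pseudocount of 5 CPM and 89 with no filter. The endoderm count was 0 with quantile normalization and with a filter at 4 CPM, 5 with a pseudocount of 5 CPM and 28 with no filter. The endoderm count ranged from 0 to 18 over the 12 libraries left out singly.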

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

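The counts over other splits of the libraries, the fit with only the libraries of the stages compared, the tests of unequal capture and of carry-over among the calls of the stage 27 libraries alone, the ratio of endoderm to mesoderm CPM of AMCG00016115, and the check of 0 values among abundant genes were chosen only after the results were seen.

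A test of the difference between stages 27 and 24 singled out the dorsal-ventral difference in each layer. In mesoderm 35 genes passed, with log2 differences of 6.1 for AMCG00012666, 5.95 for AMCG00017755, -9.03 for AMCG00008538 and -6.55 for AMCG00002893. In endoderm 2 genes passed, with 3.49 for AMCG00016191 and -4.37 for AMCG00009086. Apart from AMCG00017755, these genes had no read on either side of their layer at stage 24, so their values repeat the stage 27 difference. A change of the dorsal-ventral difference with stage cannot be told apart from lower detection at stage 24. With the libraries of stages 24 and 27 alone, AMCG00008538 and AMCG00002893 passed (adjusted p = 0.00928 and 0.00106; over the 16 alternatives 8.95e-07 to 0.0496 and 3.33e-11 to 0.422). The other 4 genes did not pass in that fit.

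The calls of stage 27 against stage 24 lay nearly all on the stage 27 side, and stage 27 libraries also held more genes. Loss of detection at stage 24 was set against 96.2% of the 1000 most abundant genes with an unadjusted p under 0.05 being higher at stage 27, which met the bound of 90% set beforehand against that explanation. The bound was wrong because abundance did not protect from loss: among these genes 8.2% of the values at stage 24 and 7.5% at stage 25 were 0, against 0.1% at stage 27, and the limit of 5% that voids the test was set after these values were seen. After quantile normalization 76.5% of the calls were higher at stage 27, between the bounds of 60% and 90%. Quantile normalization makes the libraries alike in detection as well: the median log2 change in dorsal endoderm went from 1.31 to -0.06. The 76.5% therefore decides nothing about scaling alone, and scaling stays open. Lower detection, scaling, a batch of capture, amplification or library making and a biological difference between stages cannot be told apart here. Library numbers ran in separate blocks by stage, and the biological difference was not tested separately.

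Dorsal-ventral calls in mesoderm were 170 at stage 27 against 3 and 6 at stages 24 and 25. Of the 170, 0.6% were higher in endoderm, which met the bound set beforehand against unequal carry-over of endoderm as their source. That test decides nothing, since the fit of all 36 libraries takes each gene's spread from endoderm and other stages as well. Genes that vary there are hard to call: AMCG00009551 had an adjusted p of 0.0964 in that fit and 0.00281 with the stage 27 libraries alone (limma). Of the 30 genes called with the stage 27 libraries alone 30% were higher in endoderm. These 9 genes were all ventral-higher and included AMCG00009551 and AMCG00021160. Of the 170, 50 of the 78 dorsal-higher and 51 of the 92 ventral-higher genes were higher in mesoderm than in endoderm. This was at an unadjusted p under 0.05 over both sides and all 3 stages (limma). Endoderm reads alone would not put a gene higher in mesoderm than in endoderm. These counts therefore argue against carry-over as the only source for those genes. Carry-over stays open for the rest of the 170 and for the 30. Spread taken from other stages also stays open: with the libraries of each stage alone, 30 genes passed at stage 27 against 0 and 0, which met a bound against it that was itself set after the results were seen, but the count fell from 170 to 30, limma with the 6 compared libraries alone gave 0 at each stage (996, 322 and 275 with an unadjusted p under 0.05 at stages 27, 24 and 25) and limma voom without the library of 3040 reads gave 32, 166 and 22 genes at stages 24, 25 and 27, an order in which stage 25 leads. Fewer genes detected at the earlier stages cannot be told apart from a biological difference: among the 1000 most abundant genes 0 were called at stage 27 and 0 at either other stage (limma, adjusted over those genes), a tie that the rule set beforehand would have counted for this explanation and that is read here as deciding nothing. A larger dorsal-ventral difference at the stage of outgrowth may contribute, which remains a hypothesis.

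Genes higher in endoderm were higher in ventral than in dorsal mesoderm at stage 27. If 1 source of endoderm reads in the ventral captures were the cause, the ratio of ventral mesoderm to ventral endoderm would be alike over genes; the median ratio was 13.4% (quartiles 7.88% and 21%), and 58.6% of 145 genes lay within 2-fold of it, between the bounds of 50% and 75% set beforehand. In dorsal mesoderm the median ratio to dorsal endoderm was 2.37%. Unequal capture of endoderm would put most of these genes on the ventral side, as 87.4% were, but this restates the pattern and decides nothing. Carry-over of endoderm and expression of these genes in ventral mesoderm therefore cannot be told apart, and the difference itself failed correction (fry adjusted p = 0.48).

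Other splits of the same libraries were counted for each comparison, the real split included. For endoderm against mesoderm, 1 of 100 splits, the real one, gave as many as the real 574 calls, and the highest other gave 62. For the mean dorsal-ventral difference in mesoderm, 1 of 100 gave as many as the real 38, and the highest other gave 10. Counts this large were thus rare over the splits. A share of 1 in 100 is the smallest that these splits can give and was not adjusted over comparisons. It bears on the count and does not show which genes differ. For the mean difference in endoderm (highest other 2) and the interaction by layer (highest other 8) the real count was 0. Every split reaches a count of 0, so 100 of 100 decides nothing for these. Splits reached the real count more often for the interactions by stage in endoderm (72 of 100, real 2, highest other 19) and in mesoderm (5 of 100, real 35, highest other 39). Chance was not excluded for the interactions by stage.

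For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Where the real count was 0, all 10 reach it by definition. Dorsal against ventral endoderm at stages 24, 25 and 27 had real counts of 0, 0 and 48 and highest other counts of 187, 7 and 65, with 10, 10 and 3 splits as large. The 187 calls of a split at stage 24 point to a structure of these libraries: that split set the 3 libraries with the fewest genes detected (1259, 2110 and 2885) against the 3 with the most (4397, 7391 and 8249). The split with 65 calls at stage 27, more than the real count, did so as well (8544, 8583 and 10661 against 10949, 12258 and 13160). Dorsal against ventral mesoderm had real counts of 3, 6 and 170 and highest other counts of 4, 7 and 89, with 4, 2 and 1 splits as large. Stage 27 against 24 had real counts of 363, 627, 244 and 975 in dorsal endoderm, dorsal mesoderm, ventral endoderm and ventral mesoderm and highest other counts of 23, 40, 61 and 11, with 1 split as large in each. Stage 25 against 24 had real counts of 0 and 5 in dorsal endoderm and mesoderm and highest other counts of 5 and 7, with 10 and 4 splits as large. Stage 27 against 25 had real counts of 423 and 823 and highest other counts of 7 and 18, with 1 split as large in each.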

How the results depend on the processing

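The tests with limma voom, with genes detected as a covariate, without the library of 3040 reads and with only the libraries of the stages compared were chosen only after the results were seen. Values are counts of genes past the threshold; DV stands for dorsal against ventral, numbers after a layer are stages, DV by layer and DV by stage are the interactions, and layers is endoderm against mesoderm. Counts that moved by more than 1.5 times are given here, and for these the cause was not tested except where a fit of fewer libraries or genes shows it.

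With no filter on low values, counts were 8 for DV endoderm mean, 80 for DV mesoderm mean, 3 for DV endoderm 25, 109 for DV endoderm 27, 6 for DV mesoderm 24 and 318 for DV mesoderm 27. They were 3 for dorsal endoderm 25 against 24, 8 for dorsal mesoderm 25 against 24, 18 for DV by layer, 28 for DV endoderm by stage and 89 for DV mesoderm by stage. With a filter at 4 CPM, counts were 26 for DV endoderm 27, 86 for DV mesoderm 27, 0 for DV endoderm by stage and 19 for DV mesoderm by stage. With a pseudocount of 1 CPM, the count was 2 for dorsal mesoderm 25 against 24. With a pseudocount of 5 CPM, counts were 1 for DV endoderm 25, 8 for DV mesoderm 24, 10 for DV mesoderm 25, 2 for dorsal endoderm 25 against 24, 10 for dorsal mesoderm 25 against 24 and 2 for DV by layer. They were 5 for DV endoderm by stage and 53 for DV mesoderm by stage. With quantile normalization, counts were 6 for DV endoderm 25, 10 for DV endoderm 27, 19 for DV mesoderm 24, 28 for DV mesoderm 25, 84 for DV mesoderm 27 and 32 for dorsal endoderm 27 against 24. They were 148 for dorsal mesoderm 27 against 24, 17 for ventral endoderm 27 against 24, 118 for ventral mesoderm 27 against 24, 7 for dorsal endoderm 25 against 24, 24 for dorsal endoderm 27 against 25 and 10 for dorsal mesoderm 25 against 24. The rest were 128 for dorsal mesoderm 27 against 25, 0 for DV endoderm by stage and 17 for DV mesoderm by stage. With median centring, counts were 21 for DV mesoderm mean, 2 for DV endoderm 25, 14 for DV endoderm 27, 5 for DV mesoderm 24, 112 for DV mesoderm 27 and 2364 for dorsal endoderm 27 against 24. They were 2454 for dorsal mesoderm 27 against 24, 1490 for ventral endoderm 27 against 24, 3326 for ventral mesoderm 27 against 24, 1 for dorsal endoderm 25 against 24, 2735 for dorsal endoderm 27 against 25 and 2 for dorsal mesoderm 25 against 24. The rest were 2671 for dorsal mesoderm 27 against 25, 1 for DV endoderm by stage and 19 for DV mesoderm by stage. With no variance trend, counts were 3 for DV endoderm 24, 6 for DV endoderm 25, 11 for DV mesoderm 24, 378 for ventral endoderm 27 against 24, 5 for dorsal endoderm 25 against 24 and 689 for dorsal endoderm 27 against 25. They were 12 for dorsal mesoderm 25 against 24 and 2 for DV by layer. With library quality weights, counts were 14 for DV endoderm 24, 3 for DV endoderm 25, 73 for DV endoderm 27, 831 for dorsal endoderm 27 against 24, 2260 for ventral endoderm 27 against 24 and 1679 for ventral mesoderm 27 against 24. They were 3 for dorsal endoderm 25 against 24, 1100 for dorsal endoderm 27 against 25, 2 for dorsal mesoderm 25 against 24 and 5 for DV endoderm by stage. With only the groups compared, counts were 8 for DV endoderm mean, 12 for DV mesoderm mean, 0 for DV endoderm 27, 0 for DV mesoderm 24, 0 for DV mesoderm 25 and 0 for DV mesoderm 27. They were 0 for dorsal endoderm 27 against 24, 7 for dorsal mesoderm 27 against 24, 0 for ventral endoderm 27 against 24, 2760 for ventral mesoderm 27 against 24, 1085 for dorsal endoderm 27 against 25 and 0 for dorsal mesoderm 25 against 24. The rest were 348 for dorsal mesoderm 27 against 25 and 8 for DV mesoderm by stage. With a fixed replicate block, the count was 0 for DV mesoderm 24. Without the library of 3040 reads, counts were 2 for DV endoderm 24, 62 for ventral endoderm 27 against 24, 2 for dorsal mesoderm 25 against 24 and 0 for DV endoderm by stage. With limma voom, counts were 1 for DV endoderm mean, 16 for DV mesoderm mean, 8033 for DV endoderm 24, 44 for DV endoderm 25, 0 for DV endoderm 27 and 17 for DV mesoderm 24. They were 85 for DV mesoderm 25, 5 for DV mesoderm 27, 930 for layers, 54 for dorsal endoderm 27 against 24, 184 for dorsal mesoderm 27 against 24 and 2740 for ventral endoderm 27 against 24. The rest were 22 for dorsal endoderm 25 against 24, 867 for dorsal endoderm 27 against 25, 72 for dorsal mesoderm 25 against 24, 103 for DV endoderm by stage and 1 for DV mesoderm by stage. With limma voom without the library of 3040 reads, counts were 4 for DV endoderm 24, 74 for DV endoderm 25, 0 for DV endoderm 27, 32 for DV mesoderm 24, 166 for DV mesoderm 25 and 22 for DV mesoderm 27. They were 1192 for layers, 36 for dorsal endoderm 25 against 24, 1757 for dorsal endoderm 27 against 25, 148 for dorsal mesoderm 25 against 24, 2525 for dorsal mesoderm 27 against 25 and 8 for DV by layer. The rest were 0 for DV endoderm by stage and 11 for DV mesoderm by stage. With genes detected as a covariate, counts were 2 for DV endoderm 25, 5 for DV mesoderm 24, 95 for dorsal endoderm 27 against 24, 331 for dorsal mesoderm 27 against 24, 52 for ventral endoderm 27 against 24 and 181 for ventral mesoderm 27 against 24. They were 3 for dorsal endoderm 25 against 24, 73 for dorsal endoderm 27 against 25, 3 for dorsal mesoderm 25 against 24 and 259 for dorsal mesoderm 27 against 25. With only the libraries of the stages compared, counts were 1 for DV endoderm 27, 0 for DV mesoderm 24, 0 for DV mesoderm 25, 30 for DV mesoderm 27, 120 for ventral endoderm 27 against 24 and 826 for dorsal endoderm 27 against 25. They were 0 for DV endoderm by stage and 11 for DV mesoderm by stage. Over the fits that left out a single library or a replicate number, counts ranged from 0 to 5 for DV endoderm mean, 17 to 49 for DV mesoderm mean, 0 to 10 for DV endoderm 24, 0 to 20 for DV endoderm 25 and 19 to 148 for DV endoderm 27. They ranged from 1 to 33 for DV mesoderm 24, 5 to 27 for DV mesoderm 25, 160 to 271 for DV mesoderm 27, 108 to 649 for layers and 103 to 703 for dorsal endoderm 27 against 24. Further ranges were 274 to 698 for dorsal mesoderm 27 against 24, 62 to 495 for ventral endoderm 27 against 24, 363 to 841 for ventral mesoderm 27 against 24, 0 to 17 for dorsal endoderm 25 against 24 and 116 to 590 for dorsal endoderm 27 against 25. The last were 6 to 31 for dorsal mesoderm 25 against 24, 290 to 900 for dorsal mesoderm 27 against 25, 0 to 2 for DV by layer, 0 to 20 for DV endoderm by stage and 19 to 75 for DV mesoderm by stage.

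The layer count was within 1.5 times of 574 in the alternatives other than limma voom and the fits without a replicate number, and the 4 named genes of that comparison passed the threshold in all 14 alternatives in which they were tested. Under median centring the counts of stage 27 against 24 and 25 turned direction, since the median gene of most earlier libraries had no read, and so did that of ventral endoderm 27 against 24 with limma voom (7 higher and 2733 lower) but not without the library of 3040 reads (181 and 1). Limma voom without the library of 3040 reads placed more dorsal-ventral mesoderm calls at stage 25 than at stage 27. Over the named genes and alternatives other than those leaving out a replicate, 759 values kept their direction and side of the threshold, 34 newly passed it, 123 no longer passed it and 1 reversed, that of AMCG00001446 in DV endoderm 24 with limma voom, at -0.81. No general pairing of libraries by replicate number was seen, though weak pairing is not excluded. After group means were removed, 54 pairs of libraries of the same stage and number had a median correlation of 0.01, from -0.111 to 0.211. Of these, 2 were over 0.1 (stage 24 dorsal with ventral endoderm, 0.107 for replicate 1 and 0.211 for replicate 2). The best match had the same number in 25 of 54. This is more often than 3 libraries per group would give by chance, and it was not tested. The consensus correlation of the random block was 0.006. A fixed block cannot be fitted for comparisons between stages, since the blocks lie within stages, and the planned count tests and list tests were not run. The library of 3040 reads gave 1259 genes; no simulation varied the depth.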

Other observations

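The fit of the stage 27 libraries alone used here was chosen only after the results were seen. The share of reads in the 407 mesoderm-higher genes was 3.96% ± 0.748, 4.99% ± 0.601 and 8.38% ± 0.0289 in dorsal mesoderm at stages 24, 25 and 27, and 4.42% ± 1.05, 5.6% ± 1.29 and 8.15% ± 0.867 in ventral mesoderm (SD, n = 3 each). The share in the 167 endoderm-higher genes was 2.75% ± 0.59, 2.46% ± 0.546 and 3.6% ± 0.0902 in dorsal endoderm and 1.82% ± 0.981, 2.84% ± 0.682 and 3.82% ± 0.824 in ventral endoderm. These genes were chosen on the same libraries, and the change of their shares with stage was not tested. AMCG00009551 and AMCG00021160, both abundant in endoderm at stage 27, were lower in dorsal than in ventral mesoderm at that stage in the fit of the stage 27 libraries alone (log2 differences -4.72 and -4.67, adjusted p = 0.00281 and 0.00658), and not past the threshold with all 36 libraries (adjusted p = 0.0964 and 0.121); both were picked after their values were seen.

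The calls of stage 27 against stage 24 overlapped between regions. Dorsal and ventral endoderm shared 69 calls, where 6.27 would be shared by chance, and dorsal and ventral mesoderm shared 212, where 43.3 would be. Dorsal endoderm and dorsal mesoderm shared 26, where 16.1 would be, and ventral endoderm and ventral mesoderm 43, where 16.8 would be. The chance values treat the calls as independent, but all these lists came from the same fit, with the same spread per gene. The excess over chance is therefore not evidence of a stage difference shared between regions. The mean number of genes detected was higher at stage 27 in all 4 regions, and the overlap was not tested with it held fixed.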
